A study of Fundulus heteroclitus with 36 samples.

How the data were processed

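Whole brains of 36 individual embryos of the Atlantic killifish (Fundulus heteroclitus) were profiled by RNA sequencing at 17 days after fertilisation, 6 embryos in each of 6 groups. Embryos came from 2 populations, New Bedford Harbor (NBH) and Scorton Creek (SCO). PCB126, a dioxin-like polychlorinated biphenyl that activates the aryl hydrocarbon receptor (AHR), was given to embryos at 40 or 400 ng/L from day 1 to day 7 (PCB40 and PCB400). In the SCO Hg Fed group the parents, not the embryos, had received a tuna diet high in methylmercury. The controls came from parents on a low-methylmercury salmon diet. The parental diet of the embryos given PCB126 is not given here, so whether it matched that of the controls cannot be told. RNA had been extracted with a Qiagen RNeasy Micro kit.

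Per the labels, the authors used Salmon 1.3.0 and edgeR 3.30.3, with no role or order stated. Each deposited file held 56244 RefSeq transcripts for 1 library, with expected counts (estimated reads per transcript, not normalised) and an effective transcript length in bases, both as deposited by the authors. The genome build, trimming and any filter were not stated, so no coordinates are given. All 56244 transcripts matched a gene in the RefSeq table for killifish, which gave 31637 genes. Of these, 14211 had a symbol or synonym and 17426 had only a LOC number. The 13 mitochondrially encoded genes of the table were absent from the targets, so mitochondrial RNA was not analysed here. Reads assigned to genes with only a LOC number made up 31.07% to 34.98% of a library, and no product descriptions were used. How Salmon divided reads between close paralogs cannot be checked from these values.

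Expected counts were summed per gene and rounded. Library totals ran from 38.5 to 66.4 M estimated reads (median 52.85 M), and 3 counts, the floor used here for a gene not seen, equal 0.0451 to 0.0779 counts per M reads (CPM), covering counting error only. Genes were filtered with edgeR's filterByExpr by group, which left 23292, and libraries were scaled by TMM. A single edgeR quasi-likelihood model with a mean per group was fitted to all 36 libraries, and 9 contrasts were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2 scale with their standard error (SE), and levels are group mean CPM with the standard deviation (SD, n = 6). The common biological coefficient of variation was 0.39.

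Gene lists were fixed before the data were examined. They were 32 lists of pathways and cell type markers with 505 entries, of which 397 matched a symbol or synonym and 108 did not. Matching by symbol or synonym misses members known only by a LOC number. Unmatched were cyp1b1, cyp1c1 and tiparp, among others. The microglia and leukocyte list lacked mpeg1, c1qa, c1qb, c1qc, aif1, p2ry12, mpx and lyz, and the erythrocyte list hba and hbb. The neuron differentiation list lacked dcx, tubb3, eno2, rbfox3 and neurod2. The list called mitochondrial below holds nuclear genes of mitochondrial respiration, and its entries for uqcr and cox4 to cox8 matched none. The 29 lists with at least 5 tested genes were tested with limma's camera (correlation preset to 0.01, on log2 CPM with a prior count of 2), with camera on an estimated correlation, and with fry, each adjusted over the lists of a comparison. Counts of called members were also made with p adjusted over the list alone.

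The genes named in the text followed a rule fixed at the same time. It took the 10 higher and 10 lower called genes with the smallest p that have a name for the 4 exposure comparisons and the comparison of controls, and 5 of each for the others. It added up to 3 called members per list, to at most 30 genes in a comparison, and always CYP1A and ahrr. Where fewer than 3 genes were called, the 5 with the smallest p were taken. Members named outside this rule are said to be chosen after their values were seen, and the results of some single genes are not reported here.

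The steps were tested on simulated counts with 200 genes changed: 62% of genes changed 2-fold and 93% of those changed 4-fold were recovered, 3.1% of 160 calls were false, and a comparison without changes gave 0 calls. The simulated genes varied independently, with no length trend or tissue spread, so these rates may not hold for the real libraries. Within-group pairs of libraries (90) correlated at 0.927 to 0.971 across genes, and 0 pairs were identical. File names placed all 36 libraries in 1 flow cell lane, and mean fragment lengths, from 265.4 to 295.2 bp, did not split the groups. The labels give no extraction or dissection batch, and do not say whether embryos of a group shared parents.

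A length slope was computed per library: the slope, across genes above 2 log2 CPM, of log2 expression relative to the mean of all libraries on log2 effective transcript length. Scores of pituitary, posterior hox and skeletal muscle markers, the mean log2 deviation of each set, were computed per library as measures of tissue carried along at dissection.

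Alternatives fixed before the data were examined were DESeq2's size factors (RLE in edgeR), no filter, a stricter filter (50 counts in 6 libraries), the DESeq2 test, fits of only the groups compared, replicate number as a block, an offset for effective length, limma-voom with sample weights, a threshold of 0.01 for shared genes, and leaving out each library in turn. Another 5 settings were added after seeing the data. They were the length trend removed per library as an offset, the length slope as a covariate and the 3 tissue scores as covariates. The others kept only libraries with a negative or only those with a positive length slope. These subsets needed at least 2 libraries in each group compared, so fewer libraries alone can lower their counts. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.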

Results

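The series holds brains of 36 killifish embryos: NBH Control, NBH PCB40, NBH PCB400, SCO Control, SCO Hg Fed and SCO PCB40, with n = 6 embryos each. Mean depth by group, in M estimated reads with SD, was 52.2 (7.7), 54.6 (6.8), 46.6 (5.8), 55.1 (5.2), 55.1 (2.5) and 50.6 (7.4). The 10 most abundant genes took 9.31% to 12.67% of a library. The first 2 principal components of log2 CPM held 15.1% and 10.1% of the variance. Values in brackets after a gene are its log2 fold change, SE and adjusted p. Group levels are mean CPM with SD, and n = 6 against 6 in each comparison of 2 groups, unless a setting leaves libraries out.

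The libraries differed in how expression varied with transcript length. The length slope was negative in 6 of 6 NBH Control libraries (mean -0.086, SD 0.03) and 5 of 6 NBH PCB40 libraries (-0.08, SD 0.116). It was positive in 4 of 6 NBH PCB400 libraries (0.027, SD 0.111). In Scorton Creek it was positive in 6 of 6 SCO Control libraries (0.093, SD 0.042), 6 of 6 SCO Hg Fed libraries (0.067, SD 0.041) and 3 of 6 SCO PCB40 libraries (-0.021, SD 0.149). Across the 23292 tested genes, log2 fold changes followed transcript length at a Spearman correlation of -0.36 in SCO PCB40 against SCO Control, -0.37 in NBH Control against SCO Control and 0.24 in NBH PCB400 against NBH Control. Muscle marker scores had means of -0.14 (SD 0.7), 0.1 (SD 0.73) and 0.42 (SD 0.7) in NBH Control, NBH PCB40 and NBH PCB400. They were -0.38 (SD 0.43), -0.7 (SD 0.41) and 0.7 (SD 1.01) in SCO Control, SCO Hg Fed and SCO PCB40. Pituitary scores, in the same order, were 0.34 (SD 2.91), 1.41 (SD 2.95), 0.36 (SD 4.11), -0.48 (SD 3.56), 0.83 (SD 3.02) and -2.46 (SD 3.72). Posterior hox scores were 1.49 (SD 0.72), -0.24 (SD 2.5), -1.18 (SD 1.57), -0.56 (SD 2.15), 0.71 (SD 1.37) and -0.22 (SD 2.09). The pituitary score spread more within each group than between the group means.

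**Figure D1:**
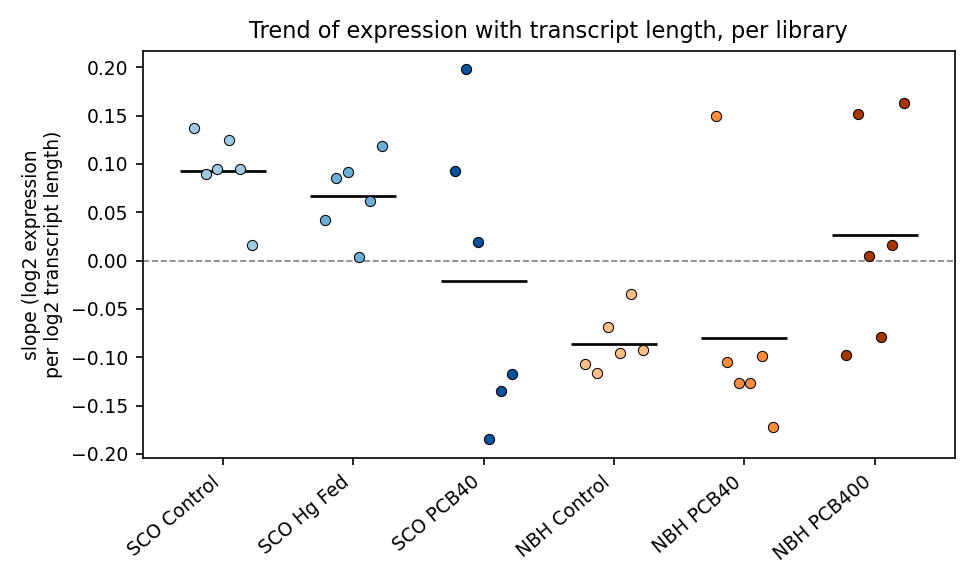
Length slope of each library (log2 expression per log2 base of transcript length) by group; points are libraries and bars are group means. All NBH Control libraries lie below 0 and all SCO Control and SCO Hg Fed libraries above, while the SCO PCB40 libraries spread over both sides.

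**Figure D2:**
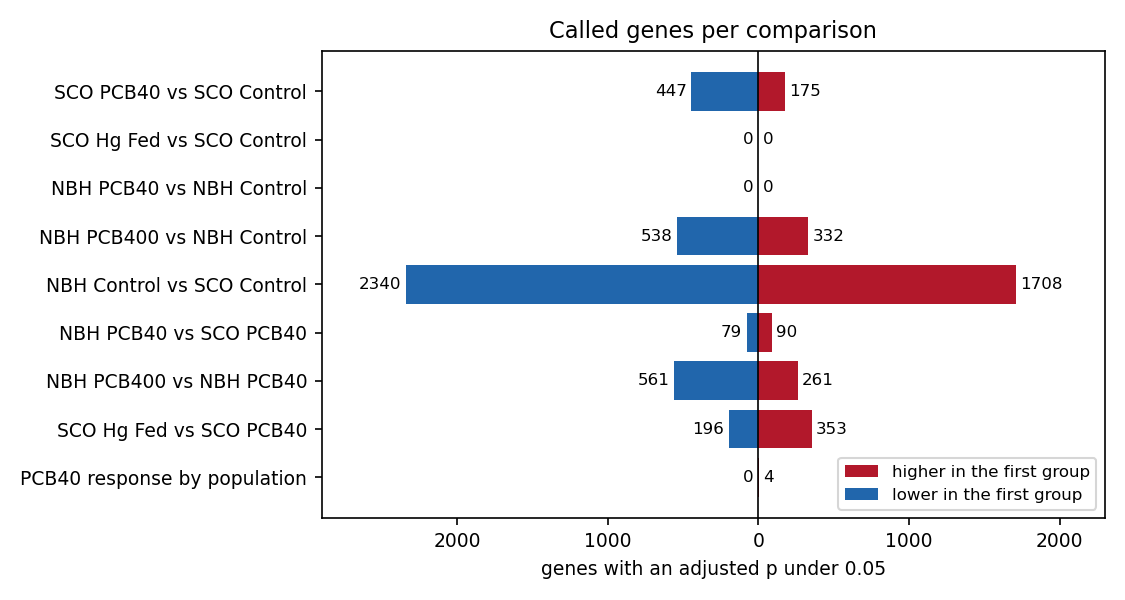
Number of genes called higher and lower at an adjusted p under 0.05 in each comparison, n = 6 per group. SCO Hg Fed and NBH PCB40, each against the control of its population, have none.

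What did the lower PCB126 dose change in Scorton Creek brains? In SCO PCB40, CYP1A, the cytochrome P450 induced through AHR, was 31-fold higher (4.96, SE 0.71, 1.49e-04), at 146 CPM (SD 63.4) against 4.71 (SD 4.33). The uncharacterised si:dkey-238o13.4 was 83.8-fold higher (6.39, SE 0.88, 1.14e-04) against controls close to the floor of 3 counts. Raised with it were si:ch211-136m16.8 (6.46-fold, 2.69, SE 0.47, 0.00104) and ncam3, named for neural cell adhesion molecules (6.17-fold, 2.63, SE 0.49, 0.00205). The AHR repressor ahrr did not pass (1.81, SE 0.58, 0.084, 4 of 6 above every control). Of the 4 measured AHR targets on the fixed list, CYP1A alone was called, and 3 passed with p adjusted over the list alone. Smaller rises were those of alg3 (0.88, SE 0.14, 6.80e-04), sumf1 (0.51, SE 0.09, 0.00133), LOC105920623 (0.98, SE 0.18, 0.00205), hcls1 (1.06, SE 0.2, 0.00205), chchd3b (0.97, SE 0.18, 0.00257) and pithd1 (0.54, SE 0.11, 0.00587, 5 of 6 above every control). Each gene named before it as higher was above every control in 6 of 6 libraries.

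More genes fell than rose. The fucosyltransferase fut9a went from 41.1 CPM (SD 12.8) to 11.3 (SD 2.5) (-1.86, SE 0.16, 1.18e-08), and kmt2e, of the trithorax-related methyltransferase family, from 12.2 (SD 1.77) to 5.03 (SD 0.917) (-1.27, SE 0.14, 3.59e-06). The signalling adaptor crk fell to 10.3 (SD 2.45) (2.07-fold, -1.05, SE 0.15, 1.68e-04). Also lower were si:ch211-183d21.3 (-1.25, SE 0.16, 3.23e-05), ubap2l (-0.71, SE 0.1, 1.27e-04), the G protein subunit gnb1b (-0.66, SE 0.1, 1.74e-04), si:dkey-175g6.2 (-0.86, SE 0.13, 1.74e-04), grid2ipa (-1.08, SE 0.17, 4.45e-04), ptpn23a (-0.77, SE 0.12, 4.45e-04) and iqsec2b (-0.95, SE 0.15, 5.67e-04). These 10 genes lay below every control in 6 of 6 libraries. Of fixed lists, the zinc transporters slc30a1a (-0.97, SE 0.22, 0.0108) and slc39a10 (-0.43, SE 0.1, 0.0169) were lower, as were the circadian repressor bhlhe41 (-0.88, SE 0.21, 0.0182) and the calcium pump atp2a2b (-0.5, SE 0.12, 0.0186, 5 of 6). So were the NMDA receptor subunit grin2ab (-0.6, SE 0.15, 0.0229, 5 of 6) and mybpc2b (-1.33, SE 0.33, 0.0259, 0 of 6 below every control but 6 of 6 below the control mean). The muscle creatine kinases ckmb (3.16, SE 0.77, 0.0216, 5 of 6) and ckma (2.94, SE 0.75, 0.0286, 5 of 6) and the GTP cyclohydrolase gch2 (0.98, SE 0.24, 0.0216, 4 of 6) were higher.

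The quasi-likelihood test called 622 genes, 175 higher and 447 lower, with 112 of them over 2-fold and 4168 at an unadjusted p under 0.05. The count was 1303 with DESeq2, 3713 with voom, 98 with only these groups and 320 with the length trend removed (151 higher, 169 lower). It was 195 with the tissue scores and 128 among libraries with a positive length slope, which keep 3 of 6 SCO PCB40 libraries. With the length slope as a covariate the count was 758, but only 329 of the 622 genes were among them. It came to 261, 377 and 290 without SCO Control replicates 1, 3 and 4, and 1469, 253 and 247 without SCO PCB40 replicates 2, 4 and 5. Of the 29 named calls, 16 held in every alternative, CYP1A, ncam3, fut9a, kmt2e and crk among them. The calls of sumf1, hcls1, pithd1, ptpn23a, slc30a1a and slc39a10 ended in 1 or more settings (highest adjusted p 0.0588, 0.0504, 0.356, 0.109, 0.0743 and 0.504), where slc39a10 went to -0.18 with the length trend removed and pithd1 to 0.3 with only positive slopes. Another 7 calls ended both in settings and without single libraries. In fits of only these groups ckmb (3.18), ckma (2.95) and the other 5 did not pass. With the tissue scores ckmb went to 0.64 and ckma to 0.57, but the muscle score among these covariates fixes this by its construction. The same covariates took gch2 to 0.7, with the length trend removed atp2a2b went to -0.21 and grin2ab to -0.33, with only positive slopes bhlhe41 to -0.55 and with voom mybpc2b to -0.63. Single libraries also ended bhlhe41 (-0.79 without SCO Control 1, -0.80 and -0.76 without SCO PCB40 4 and 5), atp2a2b (-0.48 without SCO Control 1, -0.44 without SCO PCB40 5), gch2 (0.88 and 0.94 without SCO Control 1 and 4, 0.73 without SCO PCB40 3) and ckmb (2.98 and 3.04 without SCO Control 1 and 4, 2.17 without SCO PCB40 3). The same holds for grin2ab (-0.59 and -0.55 without SCO Control 1 and 4, -0.58 and -0.60 without SCO PCB40 4 and 5), mybpc2b (-1.08 and -0.78 without SCO Control 1 and 5, -1.26 and -1.35 without SCO PCB40 4 and 5) and ckma (2.77, 2.96, 2.82 and 2.81 without SCO Control 1, 3, 4 and 5, 2.11 without SCO PCB40 3).

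**Figure D3:**
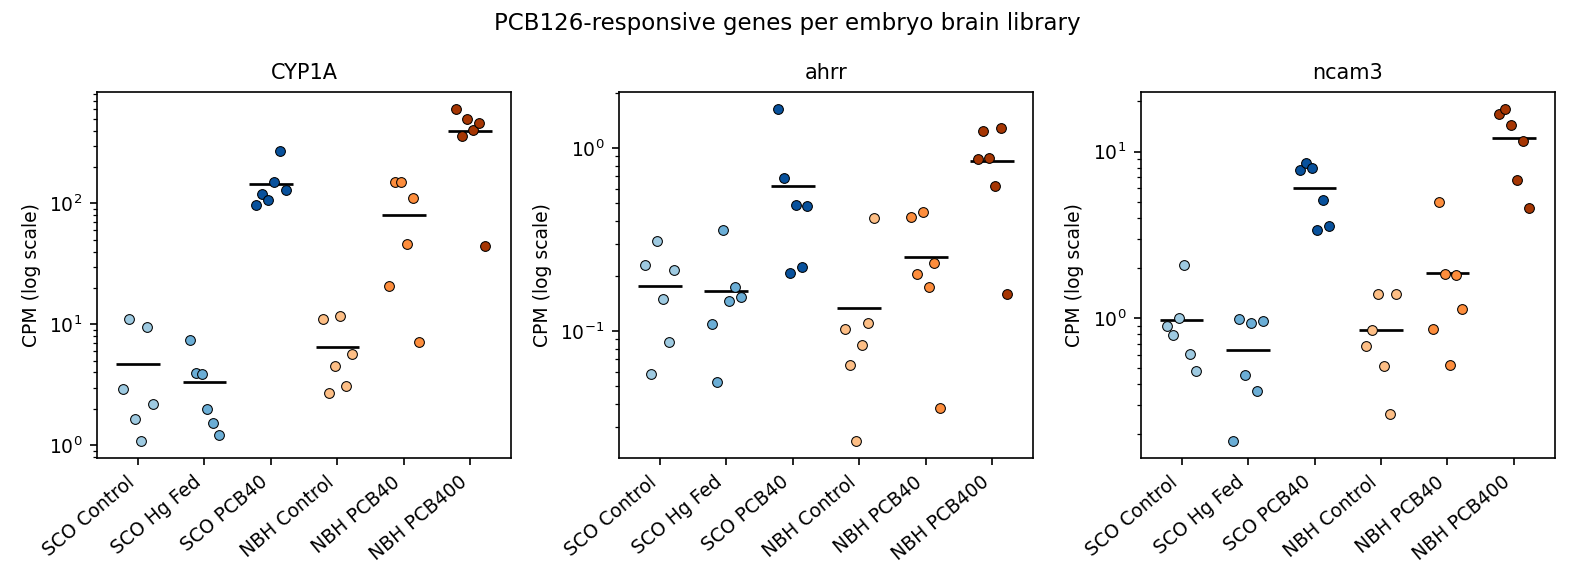
CPM of CYP1A, ahrr and ncam3 (log scale) by group; points are libraries and bars are group means. CYP1A and ncam3 are high in SCO PCB40 and NBH PCB400, and the points of SCO Hg Fed overlap those of SCO Control. CYP1A also lies above every NBH Control library in 5 of 6 NBH PCB40 libraries.

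Which groups of genes moved in SCO PCB40? The matched microglia and leukocyte markers were higher (median log2 fold change 0.51 of 12 genes, camera adjusted p 9.14e-04). The transcription factor spi1b (0.79, SE 0.22, 0.04) and granulin grna (0.69, SE 0.19, 0.04) were called, and 5 members over the list alone. Entries such as mpeg1, c1qa and aif1 had no match, so this list covers only part of the markers of these cells. Adjusted p = 0.38 with an estimated correlation, here and for the pigment, oligodendrocyte and GABA lists that follow. The 4 matched erythrocyte markers, without hba and hbb and too few for camera, had a median of 0.87, with none called and 4 over the list alone. Skeletal muscle markers were higher by camera too (median 1.78 of 15, adjusted p 9.14e-04, but adjusted p = 0.391 with an estimated correlation, 6 members called higher and 1 lower, 10 and 1 over the list alone), and the mean muscle score, 0.7, was the highest of the 6 groups. So were pigment cell markers (median 0.66 of 10, adjusted p 0.0226, 1 member called) and cell cycle genes (0.29 of 22, 0.0194, adjusted p = 0.626 with an estimated correlation, none called). Lower were oligodendrocyte markers (-0.45 of 16, 9.14e-04), with mag (-1.04, SE 0.28, 0.0401), cldn19 (-0.51, SE 0.14, 0.0481) and nkx2.2a (-0.45, SE 0.12, 0.0365) called. So was the GABA list (-0.28 of 22, 9.14e-04, 1 member called and 4 over the list alone). The members named in these sentences were chosen after their values were seen.

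Another 5 lists of neuronal and other function were lower in SCO PCB40. They were glutamate signalling (-0.25 of 26, camera adjusted p 9.14e-04, 2 members called), synaptic vesicle genes (-0.21 of 22, 0.00319, none called, 7 over the list alone), circadian genes (-0.24 of 26, 0.00486, 1 called), monoamines (-0.26 of 21, 0.00875, none called) and calcium genes (-0.14 of 21, 0.0233, 1 called). Adjusted p = 0.502 with an estimated correlation for glutamate genes, 0.391 for synaptic vesicle and circadian genes, 0.38 for monoamines and 0.618 for calcium genes. Ribosomal protein genes were lower by a small step (-0.12 of 70, 0.00224, adjusted p = 0.736 with an estimated correlation, none called). In all, 0 of the 12 lists passed with an estimated correlation. Removing the length trend ended the pigment (0.0665), glutamate (0.187), synaptic vesicle (0.102), circadian (0.0516) and calcium (0.504) lists. Microglia and oligodendrocyte markers stayed called under the other scaling, block and covariate settings, but the ribosomal list ended with the tissue scores as covariates (0.723). The muscle list cannot be tested with these covariates, since its own mean is 1 of them. The length slope as a covariate ended the pigment (0.111), cell cycle (0.29), GABA (0.123), glutamate (0.95), synaptic vesicle (0.193), circadian (0.193) and monoamine (0.0905) lists and turned the calcium list upward (0.471).

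**Figure D4:**
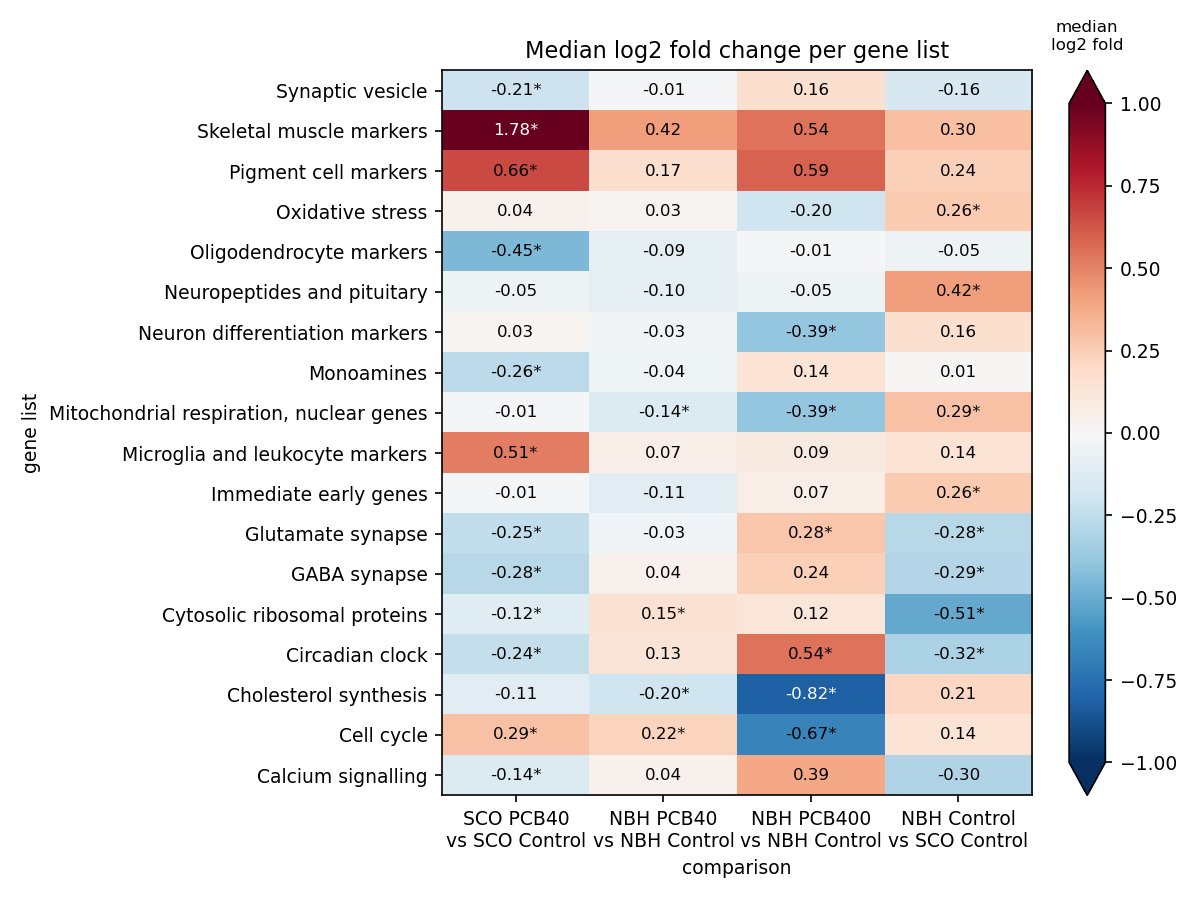
Median log2 fold change of each gene list (colour, limited to -1 and 1) in 4 comparisons; a star marks a camera adjusted p under 0.05, n = 6 per group. Cell cycle, cholesterol and mitochondrial respiration (nuclear genes) lists are lower in NBH PCB400 (adjusted p = 0.215, 0.0681 and 0.254 with an estimated correlation). Ribosomal genes are lower in NBH Control against SCO Control (adjusted p = 0.675 with an estimated correlation). There the mitochondrial list turns from higher to lower with the length slope as a covariate.

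Did the parental methylmercury diet change the offspring brain? In SCO Hg Fed no gene passed. CYP1A (-0.5, SE 0.62, 1) and ahrr (-0.08, SE 0.59, 1) were at 3.32 CPM (SD 2.3) and 0.165 (SD 0.102), against 4.71 (SD 4.33) and 0.175 (SD 0.0954). The smallest p with every library on 1 side was that of LOC105933875, at 17.3 CPM (SD 2.4) against 28.9 (SD 3.72) (-0.74, SE 0.13, 0.0504), below every control in 6 of 6. The others with the smallest p rested on part of the libraries. Among them, rasef (5.26, SE 0.99, 0.0504) and LOC105937153 (3.39, SE 0.64, 0.0504) were above every control in 3 of 6. Next came mst1ra (5.23, SE 1.08, 0.0755, 4 of 6) and dnah12 (-5.85, SE 1.12, 0.0504), which was below every control in 0 of 6. Of 29 lists, camera called 0 (smallest adjusted p 0.12, selenoproteins).

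The quasi-likelihood test called 0 genes in this comparison, with 1270 at an unadjusted p under 0.05, and DESeq2 called 77 and voom 11. Counts of 1 to 11 arose with RLE factors (4), no filter (6), the replicate block (1), the length trend removed (8) and the length slope as a covariate (11). They arose without SCO Control replicates 2, 3 and 6 (1, 4 and 4) and without SCO Hg Fed replicates 2, 3, 4, 5 and 6 (7, 1, 6, 5 and 4) as well, so the count sits at the edge of the threshold. The parents, not the embryos, received the diet, and how many clutches the 6 embryos came from is not stated.

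Did the lower PCB126 dose act in New Bedford Harbor brains? In NBH PCB40 the gene with the smallest p was CYP1A, at 80.3 CPM (SD 63.9) against 6.47 (SD 3.96), 12.4-fold (3.63, SE 0.67, 0.112) and above every control in 5 of 6 embryos, but its adjusted p did not pass. CYP1A did pass with p adjusted over the AHR target list alone. It also passed with DESeq2 (3.64) and without NBH PCB40 replicate 6 (3.87), the embryo with the lowest level, 7.14 CPM. ahrr was at 0.254 CPM (SD 0.156) against 0.133 (SD 0.14) (0.9, SE 0.6, 1). ccdc15 (1.01, SE 0.22, 0.274, 5 of 6 above every control) and LOC105927892 (-9.25, SE 1.97, 0.274, 5 of 6 below), from 14.9 CPM (SD 13) to below the floor, did not pass. Neither did ccna1 (3.68, SE 0.75, 0.274, 4 of 6) and LOC105928083 (6.85, SE 1.52, 0.274, 2 of 6). Ribosomal protein genes as a list were higher (median 0.15 of 70, camera adjusted p 2.43e-10) and nuclear genes of mitochondrial respiration lower (-0.14 of 49, 5.34e-10). Cell cycle genes were higher (0.22 of 22, 0.00153) and cholesterol genes lower (-0.2 of 16, 0.0347). Adjusted p = 0.73 with an estimated correlation for each of these 4 lists, fry called 0 of them, and no member was called.

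The quasi-likelihood test called 0 genes here, with 713 at an unadjusted p under 0.05; DESeq2 called 18 and voom 0, and 1 was called without NBH PCB40 replicate 6. The camera call of the cholesterol list ended with the length slope (0.0664) or the tissue scores (0.064) as covariates.

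What did the higher dose change in New Bedford Harbor brains? NBH PCB400 raised CYP1A 61.1-fold (5.93, SE 0.74, 3.27e-05), to 396 CPM (SD 192), and ahrr 6.16-fold (2.62, SE 0.61, 0.0161, 5 of 6 above every control). Of the 4 AHR targets these 2 were called, and of 8 AHR pathway genes 1 rose and 1 fell. ahr2, a gene of the receptor itself, rose 2.12-fold from 2.45 CPM (SD 0.245) to 5.19 (SD 1.13) (1.08, SE 0.17, 5.61e-04, 6 of 6). Again si:dkey-238o13.4 (7, SE 0.9, 3.69e-05, 5 of 6), ncam3 (3.82, SE 0.51, 7.31e-05) and si:ch211-136m16.8 (3.51, SE 0.49, 1.15e-04) were higher. They were joined by the acyl-CoA synthetase acsl5 (2.77, SE 0.45, 7.78e-04, 5 of 6), the monocarboxylate transporter slc16a1a (1.22, SE 0.2, 9.00e-04), amh (2.19, SE 0.39, 0.00218, 5 of 6), cd7al (3.22, SE 0.57, 0.00218) and bco1, which cleaves beta-carotene (1.81, SE 0.33, 0.00348, 5 of 6).

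Among the genes that fell in NBH PCB400, hspa4a, of the Hsp110 chaperone family, went from 108 CPM (SD 13.7) to 41.7 (SD 14) (-1.37, SE 0.21, 4.86e-04). hspa4b (-0.72, SE 0.15, 0.00823) and the cochaperones ppp5c (-0.91, SE 0.16, 0.0019) and ptges3b (-0.66, SE 0.16, 0.0213) were lower, but the heat shock list was not called (median -0.12 of 15, 2 called lower, camera adjusted p 0.0661). The sterol enzymes msmo1 (-1.53, SE 0.28, 0.00358), sqlea (-2.66, SE 0.52, 0.0057, 4 of 6) and CYP51 (-1.39, SE 0.28, 0.00635, 5 of 6) and the lipogenic regulator mid1ip1l (-0.96, SE 0.15, 6.83e-04) fell. So did zc3h15 (-0.48, SE 0.07, 5.61e-04), si:zfos-943e10.1 (-0.8, SE 0.13, 0.00107), cdk8 (-0.91, SE 0.16, 0.00207, 5 of 6), stx4 (-0.81, SE 0.15, 0.00262), chchd4b (-0.81, SE 0.15, 0.00284) and the cytoskeletal actin actb1 (-1.26, SE 0.23, 0.00371). Of the redox genes, gclm, for glutathione synthesis (-0.84, SE 0.18, 0.00981, 5 of 6), and thioredoxin txn (-0.6, SE 0.14, 0.0184) were lower, as was the ATP synthase subunit atp5mpl (-0.54, SE 0.13, 0.0205). The clock genes cry2 (0.51, SE 0.12, 0.0198) and tefb (0.91, SE 0.22, 0.0217, 4 of 6) rose.

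As lists, cholesterol genes (median -0.82 of 16, camera adjusted p 4.04e-11, 5 called lower and 13 over the list alone) were lower in NBH PCB400. So were cell cycle genes (-0.67 of 22, 3.64e-10, 4 and 15) and nuclear genes of mitochondrial respiration (-0.39 of 49, 2.85e-18, 7 and 34). The neuron differentiation list (-0.39 of 17, 4.73e-04, 2 and 2), in which dcx, tubb3 and rbfox3 had no match, was lower too. Adjusted p = 0.0681 with an estimated correlation for cholesterol genes, 0.215 for the cell cycle and neuron differentiation lists and 0.254 for mitochondrial genes. The mean hox score of NBH PCB400 was -1.18 against 1.49 in NBH Control. It ran from 0.11 to 2.15 in NBH Control and from -2.2 to -1.25 in NBH PCB400 apart from replicate 6 (1.93). The higher dose and the tissue carried along can thus hardly be separated by this score. Members beyond the fixed rule, chosen after their values were seen, included hmgcra (-1.37, SE 0.31, 0.0147) for sterols. For division they were aurkb (-1.05, SE 0.26, 0.0223), cdk1 (-1.04, SE 0.26, 0.026), mcm7 (-0.65, SE 0.19, 0.045) and mcm6 (-0.87, SE 0.26, 0.0496), and for neurons gap43 (-0.71, SE 0.18, 0.0248) and neurog1 (-0.64, SE 0.18, 0.0442). Circadian genes (0.54 of 26, 8.85e-06, 3 called higher and 4 over the list alone, per3 among them at 0.56, SE 0.16, 0.0433) were higher, with adjusted p = 0.215 with an estimated correlation. So were glutamate genes (0.28 of 26, 0.00162, 1 and 1, grm5b at 0.52, SE 0.15, 0.0474), with adjusted p = 0.575 with an estimated correlation. The glutamate call ended with the length trend removed (0.102) or the length slope as a covariate (0.888).

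The quasi-likelihood test called 870 genes, 332 higher and 538 lower, with 206 over 2-fold and 4809 at an unadjusted p under 0.05. The count was 1565 with DESeq2, 2748 with voom and 498 with the length slope as a covariate (283 higher, 215 lower). It was 56 with the tissue scores and 323 among libraries with a negative length slope, which leave out 4 of 6 NBH PCB400 libraries. It was 492, 309, 541, 520 and 379 without NBH Control replicates 1, 2, 3, 4 and 6, and 192, 368, 198 and 1360 without NBH PCB400 replicates 2, 3, 5 and 6. Of 30 named calls, 17 held in every alternative, among them CYP1A, ncam3, ahr2, acsl5 and hspa4a. cd7al had no adjusted p in DESeq2 (3.25). The tissue scores as covariates ended msmo1 (-1.28), ahrr (2.77), sqlea (-2.18), CYP51 (-1.15), hspa4b (-0.7) and gclm (-0.81). For ahrr, hspa4b and gclm these values lie close to those of the main fit (2.62, -0.72 and -0.84). Since the hox score nearly follows the group here, a call that ended with these covariates does not show other tissue as its source. Libraries with a negative slope alone ended stx4 (-0.66), ahrr (2.43), sqlea (-2.4) and gclm (-0.79). Settings also ended txn (-0.5 with the tissue scores, -0.51 with negative slopes, and -0.34 but called with the length trend removed), cry2 (0.4 and 0.32, and 0.35 with the slope covariate), ptges3b (-0.71 and -0.44, and -0.42), tefb (0.72 and 0.76, and 0.66) and atp5mpl (-0.51 and -0.49, and -0.32, and -0.24 with the length trend removed). Single libraries ended the same 5 calls, txn (-0.56 and -0.58 without NBH PCB400 2 and 5), cry2 (0.44 and 0.49), ptges3b (-0.59 and -0.62, both without the same libraries), atp5mpl (-0.53 without NBH PCB400 2) and tefb (0.84 without NBH Control 2, 0.84 without NBH PCB400 2).

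How did untreated brains of the populations differ? In NBH Control minus SCO Control, myelin proteolipid plp1b was 9.91-fold lower in NBH, at 38.1 CPM (SD 32.9) against 377 (SD 155) (-3.31, SE 0.69, 0.00253), and the vesicular glutamate transporter slc17a7a 6.89-fold lower (-2.79, SE 0.52, 0.00124). sfxn3 stood at 2.21 CPM (SD 0.489) against 14.5 (SD 3.64) (-2.71, SE 0.37, 9.36e-05) and the transcription factor sox4a at 42.4 (SD 13.6) against 119 (SD 17.9) (-1.49, SE 0.22, 3.13e-04). Lower in NBH with them were grid2ipa (-1.56, SE 0.17, 2.83e-06), rnf41 (-0.86, SE 0.1, 4.39e-06), si:ch211-183d21.3 (-1.17, SE 0.16, 9.36e-05), arid2 (-1.02, SE 0.14, 1.62e-04), fut9a (-1.1, SE 0.16, 2.90e-04), sipa1l3 (-1.37, SE 0.21, 3.13e-04), rc3h1b (-1.2, SE 0.18, 3.13e-04) and trak2 (-0.96, SE 0.15, 3.22e-04). Of fixed lists, so were the AHR partner arnt2 (-1.12, SE 0.21, 0.00148), rps15a (-1.28, SE 0.23, 0.00101), rpl19 (-0.6, SE 0.12, 0.00237), rps16 (-0.63, SE 0.14, 0.00358), grm5b (-0.73, SE 0.15, 0.00252) and the synaptic vesicle protein gene sv2a (-0.71, SE 0.15, 0.00382).

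Higher in NBH Control were zgc:173742 (1.31, SE 0.22, 7.91e-04), the peroxisomal pxmp2 (1.1, SE 0.18, 7.03e-04), hikeshi (1.02, SE 0.17, 7.91e-04), atp6ap1a (0.87, SE 0.15, 8.86e-04), asb6 (0.84, SE 0.15, 8.86e-04, 5 of 6), fgfbp3 (0.8, SE 0.13, 5.66e-04), gatc (0.76, SE 0.13, 8.11e-04), cd63 (0.71, SE 0.12, 8.34e-04), gbe1b (0.7, SE 0.12, 8.86e-04) and tmem128 (0.65, SE 0.11, 7.57e-04). For each named gene of both directions except asb6, 6 of 6 libraries lay beyond every library of the other group. CYP1A (0.46, SE 0.62, 0.632) and ahrr (-0.37, SE 0.6, 0.703) did not pass. Of the other AHR genes, chosen after their values were seen, AHR2 (LOC105937229), another gene than ahr2, was lower in NBH (-0.62, SE 0.21, 0.0358) and nqo1 higher (2.43, SE 0.75, 0.0248).

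As lists, ribosomal protein genes were lower in NBH Control (median -0.51 of 70, camera adjusted p 6.95e-17, 47 called lower and 57 over the list alone), as were circadian (-0.32 of 26, 0.0052, 6 and 9), GABA (-0.29 of 22, 0.0236, 5 and 5) and glutamate genes (-0.28 of 26, 0.00181, 4 and 4). Adjusted p = 0.675 with an estimated correlation for these 4 lists. Nuclear genes of mitochondrial respiration (0.29 of 49, 1.42e-07, 14 called higher and 24 over the list alone) and immediate early genes (0.26 of 19, 0.0358, 3 and 3) were higher. So were neuropeptides (0.42 of 21, 0.0277, 4 and 4) and oxidative stress genes (0.26 of 17, 0.0487, 4 and 6). For these 4 higher lists, adjusted p = 0.675 with an estimated correlation, or 0.692 for neuropeptides. With the length slope as a covariate the mitochondrial list turned lower (0.484) and the glutamate list higher (0.733), and the circadian (0.413), GABA (0.995), neuropeptide (0.675) and oxidative stress (0.775) calls ended. Removing the trend ended the circadian (0.148), GABA (0.432), glutamate (0.432), immediate early (0.148), neuropeptide (0.361) and oxidative stress (0.435) calls. The tissue scores ended the immediate early (0.103) and oxidative stress (0.053) calls.

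In the quasi-likelihood test 4048 genes passed, 1708 higher and 2340 lower in NBH Control. Of these, 1079 were over 2-fold, and 7725 genes had an unadjusted p under 0.05. The count was 6270 with only these groups, 7333 with voom, 2591 with the length trend removed, 538 with the length slope as a covariate and 1258 with the tissue scores. Without single libraries it ran from 2746 to 3947. The length slope as a covariate also ended the calls of slc17a7a (-1.74, adjusted p 0.0546), grm5b (-0.41, 0.0885), rps16 (-0.52, 0.0623) and sv2a (-0.28, 0.117). It left arnt2 called at -0.5 (0.0282), and other calls also shrank by more than 1.5 times but passed: sox4a (-0.99), rps15a (-0.8), arid2 (-0.66), fgfbp3 (0.5), gatc (0.49), cd63 (0.45), gbe1b (0.41) and tmem128 (0.38). With the trend removed trak2 stood at -0.63. All NBH Control libraries have a negative slope and all SCO Control libraries a positive one, so population and length slope cannot be separated within these groups.

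Did the populations differ after the same low dose? Between NBH PCB40 and SCO PCB40, CYP1A (-0.86, SE 0.6, 0.502) and ahrr (-1.28, SE 0.57, 0.277) did not pass. The PCB126-raised si:dkey-238o13.4 was lower in NBH PCB40, at 0.309 CPM (SD 0.349) against 6.31 (SD 4.67) (-4.31, SE 0.77, 0.00746, 6 of 6). plp1b was lower, as in the controls (-3.98, SE 0.71, 0.00746, 4 of 6), with sipa1l3 (-1.14, SE 0.2, 0.00762, 6 of 6), spry2 (-0.53, SE 0.1, 0.0102, 6 of 6) and sox4a (-1.18, SE 0.22, 0.0103, 6 of 6). gm2a (1.53, SE 0.27, 0.00743, 6 of 6), spock3 (0.81, SE 0.15, 0.0102, 4 of 6), pde6gb (1.78, SE 0.34, 0.0118, 5 of 6), dnajc18 (1.76, SE 0.36, 0.0175, 5 of 6) and elmo1 (1.66, SE 0.34, 0.018, 5 of 6) were higher.

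Here 169 genes passed, 90 higher and 79 lower, 114 of them over 2-fold. Of all tested genes, 3592 had an unadjusted p under 0.05. The count was 622 with DESeq2, 8 with only these groups, 11 with voom and 38 with the tissue scores. It was 2 among libraries with a negative slope, which leave out 3 of 6 SCO PCB40 and 1 of 6 NBH PCB40 libraries. It was 485, 71, 85, 103, 303 and 38 without NBH PCB40 replicates 1 to 6 in turn, and 85, 67, 104 and 365 without SCO PCB40 replicates 1, 2, 3 and 6. Each of the 10 named calls ended in 1 or more settings (highest adjusted p 0.108 for si:dkey-238o13.4 to 0.349 for sipa1l3). The calls of dnajc18 (1.55) and elmo1 (1.53) ended without NBH PCB40 replicate 6. Of the called genes, 58 were higher and 40 lower in NBH in both population comparisons and 1 had opposite signs, where 6.6 and 7.94 would be shared if calls were independent. Log2 fold changes correlated at r = 0.6 across genes, which are not independent replicates.

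What did the higher dose add within New Bedford Harbor? NBH PCB400 exceeded NBH PCB40 in si:dkey-238o13.4 (5.3, SE 0.8, 0.00165, 5 of 6), slc16a1a (1.24, SE 0.2, 0.00343, 6 of 6), acsl5 (2.64, SE 0.44, 0.0047, 5 of 6), ncam3 (2.69, SE 0.48, 0.00722, 5 of 6) and gpr173 (0.53, SE 0.1, 0.00722, 5 of 6). CYP1A was 4.94-fold higher (2.3, SE 0.63, 0.0368, 5 of 6), and ahrr did not pass (1.73, SE 0.58, 0.0829). Lower at the higher dose were the arginine methyltransferase carm1 (-0.84, SE 0.15, 0.00677), hspa4a (-1.11, SE 0.21, 0.00749, 5 of 6), the mitotic kinesin kif2c (-1.3, SE 0.24, 0.00783), mid1ip1l (-0.8, SE 0.15, 0.00833) and poglut1 (-1.09, SE 0.21, 0.00833).

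This comparison had 822 called genes, 261 higher and 561 lower, 225 of them over 2-fold. An unadjusted p under 0.05 was reached by 4697. The count was 1593 with DESeq2, 126 with only these groups, 2813 with voom, 371 with the length slope as a covariate (180 higher, 191 lower), 390 with the tissue scores and 250 among libraries with a negative slope. It was 2615, 494, 240, 102 and 429 without NBH PCB40 replicates 1, 3, 4, 5 and 6, and 155, 342, 102 and 1526 without NBH PCB400 replicates 2, 3, 5 and 6. The CYP1A call ended without NBH PCB40 replicates 4 (2.18), 5 (2.42) and 6 (2.06), without NBH PCB400 replicates 1 (2.14), 2 (2.33), 3 (2.23) and 5 (2.25), and in 3 settings (highest adjusted p 0.122). Fits of only these groups ended acsl5 (2.62) and gpr173 (0.5), and libraries with a negative slope alone ended ncam3 (2.5), kif2c (-1.02) and poglut1 (-0.83).

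How did the parental diet and direct PCB126 differ in Scorton Creek? Between SCO Hg Fed and SCO PCB40 the PCB126 genes stood apart: CYP1A was 43.9-fold lower in SCO Hg Fed (-5.45, SE 0.73, 6.82e-05), with si:dkey-238o13.4 (-6.03, SE 0.86, 1.83e-04), ncam3 (-3.23, SE 0.5, 4.78e-04), si:ch211-136m16.8 (-2.85, SE 0.47, 0.00103) and alg3 (-0.81, SE 0.14, 0.00266, 5 of 6). fut9a (1.83, SE 0.16, 1.85e-08), kmt2e (1.02, SE 0.14, 1.83e-04), the ubiquitin ligase rlim (0.97, SE 0.14, 2.22e-04), si:ch211-183d21.3 (1.03, SE 0.16, 4.78e-04) and ajm1 (0.72, SE 0.11, 4.78e-04) were higher in SCO Hg Fed. Each named gene but alg3 separated 6 of 6 libraries from the other group. ahrr did not pass (-1.89, SE 0.59, 0.0762).

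Calls numbered 549, 353 higher and 196 lower, 200 of them over 2-fold. At an unadjusted p under 0.05 there were 4002. The count was 1120 with DESeq2, 45 with only these groups, 2289 with voom, 890 with the length slope as a covariate, 62 with the tissue scores and 190 among libraries with a positive slope. It was 360, 327 and 312 without SCO Hg Fed replicates 3, 5 and 6, and 1017, 263 and 289 without SCO PCB40 replicates 2, 4 and 5. Settings ended the calls of si:ch211-183d21.3, ajm1 and alg3 (highest adjusted p 0.0648, 0.0655 and 0.0757).

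Did the response to the lower dose depend on population? The interaction, the NBH PCB40 effect minus the SCO PCB40 effect, passed for 4 genes. fut9a (1.56, SE 0.23, 0.00158), kmt2e (1.24, SE 0.2, 0.00728), si:ch211-183d21.3 (1.27, SE 0.22, 0.0164) and crk (1.16, SE 0.21, 0.0305) fell in SCO PCB40, in 6 of 6 libraries below every control, while no gene passed in NBH PCB40. In NBH Control they already stood low: fut9a at 19.2 CPM (SD 3.09), 15.6 (SD 1.56) in NBH PCB40, and crk at 13.6 (SD 1.62) and 14.6 (SD 2.35). fut9a and si:ch211-183d21.3 are also among the genes that set SCO Control and SCO Hg Fed apart from all other libraries. For those genes, handling shared by these groups could not be told apart (pattern 2 below). Neither CYP1A (-1.33, SE 0.86, 0.665) nor ahrr (-0.91, SE 0.83, 0.775) passed. Of the other genes raised by PCB126 in SCO, looked up after their values were seen, si:dkey-238o13.4 (-4.69, SE 1.22, 0.192) and ncam3 (-1.5, SE 0.66, 0.492) did not pass either.

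**Figure D5:**
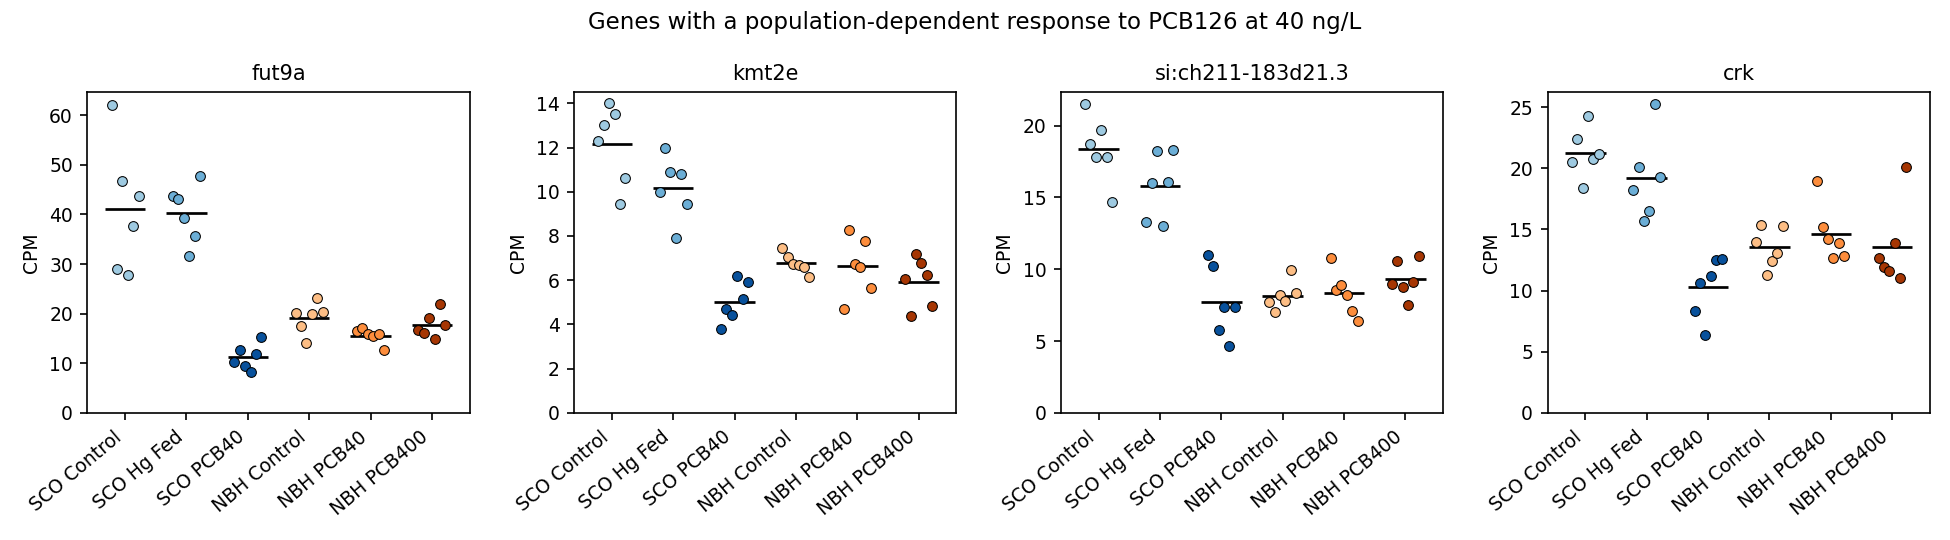
CPM of fut9a, kmt2e, si:ch211-183d21.3 and crk by group; points are libraries and bars are group means. SCO Control and SCO Hg Fed are high, and SCO PCB40 lies at the level of the NBH groups or below.

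As lists, the interaction was positive for ribosomal (median 0.28, camera adjusted p 4.62e-10), circadian (0.28, 0.00179), GABA (0.24, 0.00896), glutamate (0.28, 0.0033) and oligodendrocyte genes (0.31, 0.0172), and negative for microglia (-0.57, 8.55e-04) and muscle markers (-1.31, 0.00572). Adjusted p = 0.579 with an estimated correlation for each, fry called 0, and no member was called. The length slope as a covariate ended the circadian (0.0691), GABA (0.523), glutamate (0.991), oligodendrocyte (0.238) and muscle (0.0619) lists. Removing the trend itself ended GABA (0.202) and glutamate (0.383), and the tissue scores ended oligodendrocyte (0.0605). The 4 calls compare with 2136 genes at an unadjusted p under 0.05. The count was 76 with DESeq2, 228 with voom, 2 with only these groups, 8 with the effective length offset and 1 with the tissue scores. It was 8 without NBH Control replicate 5, 2 and 10 without NBH PCB40 replicates 1 and 6, 7 without SCO Control replicate 6, and 9 and 32 without SCO PCB40 replicates 1 and 2. fut9a held in every alternative. kmt2e ended with the length trend removed (0.96) or the tissue scores (1.20) and si:ch211-183d21.3 with only these groups (1.27), the tissue scores (1.13) and without NBH PCB40 replicate 1 (1.18). The crk call ended in 4 settings (highest adjusted p 0.209) and without NBH Control 1, 3 and 4 (1.17, 1.11, 1.14), NBH PCB40 1, 2 and 3 (1.07, 1.15, 1.17) and SCO Control 2, 4 and 5 (1.14, 1.12, 1.17).

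Did exposures that share a control shift the same genes? SCO PCB40 and SCO Hg Fed shared 0 called genes, since SCO Hg Fed had none, and their log2 fold changes correlated at r = 0.33 across genes. This compares with 0.49 (SD 0.02) in 20 simulations where the shared SCO Control alone links them. With 3 control libraries for each exposure, the median of 10 divisions was 0.01 (-0.07 to 0.11). NBH PCB400 and NBH PCB40 shared 0 called genes, with r = 0.34 against 0.5 (SD 0.01) simulated and -0.03 (-0.13 to 0.07) with divided controls. The simulated exposed groups held no response, so an r below the simulated one cannot show that no shift was shared. The covariance was 0.101 against 0.097 simulated for the SCO pair and 0.091 against 0.101 for the NBH pair. With divided controls r took both signs in each pair, across genes that are not independent replicates.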

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

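The tests of the 3 patterns below were chosen after the results they measure had been seen, apart from the count of other divisions of the libraries for the third, whose 2 lists had been joined because both fell, and the first 2 patterns were tested in several versions, whose earlier values are given. The counts of other splits were planned before the data were examined.

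Single libraries stood apart from the other 5 of their group, by a gap above 0.625 of the group's range, in 19 of 108 groups of 6 values. Chance gives about 1 in 20 groups if values are independent and normally distributed. CPM values need not be so, and the groups share libraries, so an excess over chance cannot be read from this number. The length slope did so in NBH PCB40 replicate 1 (0.15, others -0.172 to -0.099). The pituitary score did in NBH PCB40 replicate 6 (-4.58, others 2.02 to 2.96) and SCO Hg Fed replicate 4 (-5.11, others 0.55 to 2.86). The hox score did in NBH Control replicate 5 (0.11, others 1.44 to 2.15), NBH PCB400 replicate 6 (1.93, others -2.2 to -1.25) and SCO Hg Fed replicate 3 (-1.9, others 0.63 to 1.84). In CPM, CYP1A did in SCO PCB40 replicate 5 (270, others 97.8 to 151), ahrr in NBH Control replicate 6 (0.412, others 0.025 to 0.111) and SCO PCB40 replicate 1 (1.64, others 0.207 to 0.686), si:dkey-238o13.4 in NBH PCB40 replicate 5 (0.988, others 0.0189 to 0.293). Also in CPM, ncam3 did in NBH PCB40 replicate 2 (4.97, others 0.52 to 1.83) and SCO Control replicate 4 (2.09, others 0.482 to 1). The receptor gene ahr2 did in SCO Hg Fed replicate 2 (3.72, others 2.9 to 3.13), ckma in NBH Control replicate 5 (8.99, others 0.631 to 3.46), NBH PCB40 replicate 6 (11.9, others 0.724 to 4.71) and SCO PCB40 replicate 3 (29.9, others 1.3 to 11.2). Last, fut9a did in NBH PCB40 replicate 6 (12.6, others 15.4 to 17.1), crk in NBH PCB400 replicate 6 (20.1, others 11 to 13.9) and slc17a7a in NBH PCB400 replicate 2 (6.84, others 0.445 to 1.49). The 4 genes whose PCB40 effect differed between the populations by the interaction test were fut9a (1.56), kmt2e (1.24), si:ch211-183d21.3 (1.27) and crk (1.16).

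Pattern 1 is the set of 450 genes that passed with an over 2-fold difference of the same sign in NBH Control against both SCO Control and SCO Hg Fed, scaled so that SCO Control and SCO Hg Fed lie near 0 and NBH Control near 1. The 3 exposed NBH libraries with a length slope above 0.1 (NBH PCB40 replicate 1, NBH PCB400 replicates 2 and 6) stood at 0.19 to 0.28 (median 0.24) and the other 9 at 0.75 to 1.15, so much of this set may follow the transcript length trend rather than population; SCO PCB40 libraries with a negative slope stood at 0.64 to 0.71 and those with a positive slope at -0.11 to 0.51. Wrong population labels of the PCB126-exposed libraries are argued against, over the 110 of these genes with an over 4-fold difference in both. The lowest exposed NBH library lay 0.16 above the highest SCO Control or SCO Hg Fed library, and SCO PCB40 lay 0.3 below NBH Control. Labels of NBH Control, SCO Control and SCO Hg Fed were not tested, since the genes were chosen on these libraries. Among the exposed libraries, the lowest of NBH stood at 0.27 and the highest of SCO PCB40 at 0.16. NBH PCB40 replicates 4 and 5 (0.27 and 0.28) lay below every NBH Control library (lowest 0.46). An earlier version, on 63 genes with the slope as a covariate, put the lowest exposed NBH library 0.13 above the highest SCO PCB40 library. Whether the slope comes from handling, RNA quality or a different mix of cells stays open, since long neuronal transcripts would shift with maturity too, and this was not tested.

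Pattern 2 is a set of 15 genes, among them fut9a, si:ch211-183d21.3, grid2ipa, gnb1b, ubap2l, casd1 and lrrc4.1, that separates the 12 SCO Control and SCO Hg Fed libraries from the other 24; of the 15 ways to set 2 groups against 4, no other gave any gene. The median difference between SCO PCB40 and SCO Control went from -0.75 to -0.6 with the trend removed and to -0.64 with the slope as a covariate. With the trend removed, 7 of the 15 still separated the libraries. But the genes were chosen because every SCO PCB40 library lay beyond every SCO Control library. This choice favours a difference that remains, so these values cannot decide whether the length trend is the whole cause. NBH material in the SCO PCB40 tubes is argued against by the over 4-fold population genes, which were chosen without SCO PCB40. On the linear scale they stood at 0 to 0.04 in SCO PCB40. The 15 genes stood at 0.77 to 1.23 there, which their choice on these libraries favours. The first position was under 0.5 of the second in 6 of 6 libraries. Of earlier versions, the 450 genes gave 2 of 6 and the slope covariate 6 of 6. The share of genes off a common position (14.7% and 1.3%) decided nothing, and 0 genes were over 20-fold apart in every library. Handling shared by SCO Control and SCO Hg Fed cannot be told apart from the absence of both PCB126 and NBH descent, because the labels give no batch within these groups (15 genes); fragment lengths did not divide the libraries this way. A response of these genes to PCB126 in SCO embryos, at levels NBH embryos have without it, may thus remain as a hypothesis.

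Pattern 3 is the fall of the 38 cell cycle and cholesterol genes in NBH PCB400 (median -0.77). It stayed at -0.72 with the length trend removed and -0.7 with the slope as a covariate, which argues against the length trend as the whole cause. With the tissue scores as covariates it stayed at -0.66. This argues less firmly against other tissue, since the hox score divides these groups apart from NBH PCB400 replicate 6. Of 462 divisions of the 12 libraries, 1, the real one, gave a shift as large (-0.79 on mean log2 CPM, highest other 0.72 in size), but the lists were picked from 29 for falling in these libraries, so a chance division stays open. Each NBH PCB400 library lay below every NBH Control library, at -1.13 to -0.5 against -0.34 to 0.24, and without single NBH PCB400 libraries the median was -0.86 to -0.68. An effect of PCB126 stays open too and was not tested further; at the lower dose the cell cycle list was higher instead by camera, in SCO PCB40 (median 0.29, adjusted p 0.0194, but adjusted p = 0.626 with an estimated correlation) and NBH PCB40 (0.22, 0.00153, but adjusted p = 0.73 with an estimated correlation).

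Other splits of the same libraries were refitted, 100 per comparison with the real one included. For SCO PCB40 1 split gave as many calls (622, highest other 161), for NBH PCB400 1 (870, highest other 31), for NBH Control against SCO Control 1 (4048, highest other 323). For NBH PCB400 against NBH PCB40 the number was 3 (822, highest other 1565), for SCO Hg Fed against SCO PCB40 1 (549, highest other 278) and for the interaction 4 (4, highest other 14). Taken 1 comparison at a time, with no allowance for 9, the share is under 0.05 for SCO PCB40, NBH PCB400, the controls and SCO Hg Fed against SCO PCB40. This argues against a random division of embryos that could be exchanged freely. It cannot exclude shared parents or batches, which the labels do not give. For NBH PCB400 against NBH PCB40 and the interaction the share is under 0.05 as well, but another split called more genes than the real one, so less rests on it. Chance cannot be excluded for NBH PCB40 against SCO PCB40 (169, 9 splits, highest other 2864). For SCO Hg Fed (0, 100 splits, highest other 4) and NBH PCB40 (0, 100 splits, highest other 136) the real count of 0 fixes the result, so the splits say nothing. A split with 2864 calls points to a structure of the samples beyond their groups. Over the other splits of that comparison calls rose with the gap in mean length slope between the sides (Spearman correlation 0.51). Among libraries with a negative slope alone the real comparison called 2 genes. That subset leaves out 3 of 6 SCO PCB40 and 1 of 6 NBH PCB40 libraries, so lost power could lower the count as well.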

How the results depend on the processing

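Counts of called genes moved by more than 1.5 times, or away from 0, in the settings below, and the cause was not tested. SCO PCB40 against SCO Control (622) gave 1303 with DESeq2, 98 with only the groups compared, 3713 with voom, 320 with the length trend removed, 195 with the tissue scores and 128 with only positive slopes. The slope covariate moved this count less, to 758, but only 329 of the 622 genes were still called. SCO Hg Fed (0) gave 4 with RLE, 6 with no filter, 77 with DESeq2, 1 with the replicate block, 11 with voom, 8 with the trend removed and 11 with the slope covariate, and NBH PCB40 (0) gave 18 with DESeq2. NBH PCB400 (870) gave 1565 with DESeq2, 2748 with voom, 498 with the slope covariate, 56 with the tissue scores and 323 with only negative slopes. NBH Control against SCO Control (4048) gave 6270 with only the groups compared, 7333 with voom, 2591 with the trend removed, 538 with the slope covariate and 1258 with the tissue scores. In the order DESeq2, only the groups compared, voom, tissue scores, NBH PCB40 against SCO PCB40 (169) gave 622, 8, 11 and 38 (2 with only negative slopes) and NBH PCB400 against NBH PCB40 (822) 1593, 126, 2813 and 390 (371 with the slope covariate, 250 with only negative slopes). In the same order, SCO Hg Fed against SCO PCB40 (549) 1120, 45, 2289 and 62 (890 with the slope covariate, 190 with only positive slopes), and the interaction (4) 76, 2, 228 and 1 (8 with the effective length offset). Without single libraries the counts ran from 247 to 1469 for SCO PCB40, 0 to 7 for SCO Hg Fed, 0 to 1 for NBH PCB40, 192 to 1360 for NBH PCB400, 2746 to 3947 for the controls, 38 to 485 for the PCB40 groups, 102 to 2615 for NBH PCB400 against NBH PCB40, 263 to 1017 for SCO Hg Fed against SCO PCB40 and 2 to 32 for the interaction. Lists called by camera went from 12 to 6 in SCO PCB40, 0 to 1 in SCO Hg Fed and 7 to 4 in the interaction with the slope covariate, and from 8 to 2 in the controls with it or with the trend removed. An estimated correlation left 0 in each of the 6 comparisons with list tests, and fry 7, 0, 0, 6, 5 and 0. Genes shared by SCO PCB40 and SCO Hg Fed went from 0 to 1 with RLE, no filter, the trend removed or the slope covariate. Those shared by both population comparisons went from 98 to 57 with the slope covariate, 20 with the tissue scores and 8 at a threshold of 0.01. Signs reversed, in genes that had not passed, for ahrr in SCO Hg Fed (-0.46 to 0.16 without single libraries, above 0 without SCO Control 1, 0.01, or 3, 0.16, and SCO Hg Fed 1, 0.01, or 2, 0.10) and in the controls with the slope covariate for CYP1A (-0.31) and ahrr (0.13). Named-gene values were counted as kept if their sign and their state, called or not called, did not change, whatever their size. Of 144, 140 were kept with RLE and with no filter, 132 with DESeq2, 141 with the block, 144 with the length offset, 134 with voom, 130 with the trend removed, 127 with the slope covariate and 117 with the tissue scores, and so were 127 of 127 with the stricter filter. Calls ended for 30 of 135 with only the groups compared, 10 of 48 with only positive slopes and 23 of 60 with only negative slopes. The replicate block gave 644, 1, 0, 1039, 4147, 117, 821, 476 and 5 calls, and ended ckmb (2.72, adjusted p 0.0526), ckma (2.6, 0.0523) and mybpc2b (-1.18, 0.0566) in SCO PCB40. The labels do not say that replicate numbers pair embryos. The 90 same-number pairs correlated at -0.29 to 0.36 (median 0.01), 7 of them over 0.1, and 14 of 36 libraries stood closest to their own number, where about 1 in 6 would by chance, so a weak link between some same-numbered libraries stays open. The share of calls that were higher moved from 28.1% to 47.2% in SCO PCB40 with the trend removed and from 38.2% to 56.8% in NBH PCB400 with the slope covariate. The settings on length slope and tissue scores were added after seeing the data; slope subsets were not run where a group had too few libraries of 1 sign.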

Other observations

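PCB126 had a small set of genes in common between the populations. This comparison of SCO PCB40 and NBH PCB400, which share no library, was chosen after the data were examined. Of their calls, 27 genes were higher in both, 5 lower in both and 6 opposite, against 2.49 and 10.3 expected for the first 2 if calls were independent. Beside CYP1A, ncam3, si:dkey-238o13.4 and si:ch211-136m16.8, the genes higher in both included chchd3b (0.97 in SCO PCB40, 0.86 in NBH PCB400), the hypoxia-inducible prolyl hydroxylase egln3 (0.91, 1.18), the carotenoid enzyme bco1 (1.37, 1.81), the immune genes tlr21 (1.32, 1.47), hcls1 (1.06, 0.85) and vsir (0.79, 0.85), and the connexin cx32.3 (1.22, 1.12). Lower in both were tmsb4x (-0.42, -0.5), stx16 (-0.63, -0.36) and seta (-0.79, -0.63). With the length trend removed the numbers were 23 higher, 7 lower and 0 opposite, against 2.63 and 3.19 expected for the first 2. The genes lower in both thus turned from fewer than expected to more.

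Log2 fold changes of the 2 comparisons correlated at r = 0.06 across genes, which are not independent replicates, and at 0.13 with the length trend removed. ahr2 passed in NBH PCB400 only, and whether it differs from SCO PCB40 was not tested, as dose and population both differ.

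NBH PCB400 replicate 6 stood near the NBH PCB40 libraries. Over 200 genes that separate NBH PCB400 from NBH PCB40 without it, scaled to 0 and 1 and so chosen to place the other 11 libraries apart, it stood at 0.1, against 0.86 to 1.28 in the other NBH PCB400 libraries and -0.38 to 0.24 in NBH PCB40. Its CYP1A level was 44.5 CPM, against 358 to 608 in the others. Leaving it out raised the NBH PCB400 count from 870 to 1360. No NBH PCB40 library stood among the others of NBH PCB400, and no explanation was tested.

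Among the NBH PCB40 embryos CYP1A ran from 7.14 to 149 CPM, against 2.72 to 11.8 in NBH Control. The adjusted p over all tested genes was 0.112, and leaving out replicate 6 moved the log2 fold change from 3.63 to 3.87.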
